A study of Arabidopsis thaliana with 59 samples.

How the data were processed

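Small RNAs were measured in 59 libraries from 27 organ and stage groups of Arabidopsis thaliana Columbia. Per the labels, total RNA was extracted with Trizol, small RNA was enriched with PEG and cut from gels at 18 to 28 nt, and plants grew in long days. The deposited files list each distinct sequence of 18 to 28 nt with its read counts. These were whole numbers in every file and were taken as raw counts without scaling. The authors name Bowtie and TAIR10 without versions. In a check, 20000 reads drawn from each library matched the TAIR10.1 reference exactly in 100% of cases. No library was a copy of another and no sequence was listed more than once in a library. Replicate 1 of flower stage 9 totals exactly 4500000 reads, for which the labels give no reason.

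Mature miRNAs were taken from the RefSeq annotation of TAIR10.1 (5 nuclear chromosomes), which gives 428 mature positions, 350 distinct sequences and 214 families. Reads identical in sequence and length to a mature miRNA were counted. A sequence made at several loci was counted once, and 45 of the 350 came from more than 1 annotated locus. Matches to ribosomal RNA were counted on the same reads. Repeat libraries of a replicate were summed, which gave 54 biological replicates, 2 per group.

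Counts were fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling of the miRNA counts, one quasi-likelihood model over the 27 groups, 27 residual degrees of freedom and no term for the replicate number. The filterByExpr filter (minimum count 10, minimum total 15) left 216 miRNAs from 122 families, which held 99.97% of miRNA reads. The common dispersion was 0.7714, a coefficient of variation of 87.8%. TMM factors ran from 0.251 to 2.24. A call required a Benjamini-Hochberg adjusted p below 0.05. One test asked whether a miRNA differed among the groups, one whether a group differed from the mean log2 level of the others, and 13 contrasts compared named groups. An enrichment call also required an estimate of at least 4-fold, a limit that was not itself tested. The comparisons, the miRNA lists, the naming rule and the other settings to try were fixed before the data were examined. MiRNAs were named when they passed the threshold with a change of at least 2-fold and a mean of at least 10 CPM over the contrast's libraries. The libraries of the 2 sides also had to not overlap. Up to 10 higher and 10 lower were named per contrast. Up to 3 enriched miRNAs per group with at least 10 CPM there, the up to 4 most abundant members per list and the 10 most abundant miRNAs were also named. Some further list members were named for their values, outside these limits.

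Where a side of a contrast had 0 reads, the ratio was bounded with 3 reads over the group. Where it had 1 to 3 reads, the ratio is given with a 95% counting interval. Lists were tested with fry from limma through edgeR. Its directional p asks whether members move on balance one way and its mixed p whether they change in either direction, with adjustment over the 195 pairs of list and contrast. Members were also adjusted over the list alone.

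The 24-nt share and the correlation of miR156 and miR157 with miR172 were tested with permutations of the groups, exact for the share and with 100000 resamples for the correlation (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Shares carry 95% Wilson intervals, the widest being ± 0.0723 points for ribosomal RNA, ± 0.0652 for 24-nt reads and ± 0.0489 for miRNAs. Genome matches used bwa 0.7.19-r1273 and samtools 1.23.1, and plots matplotlib 3.10.9. DESeq2 1.42.0 served as the other tool.

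The replicate number acted like a batch, and whether its cause was technical or biological was not settled. Of the 216 miRNAs 103 differed with the replicate number across groups (41 higher and 62 lower in replicate 2), and replicate 1 libraries held 3483514 to 6412670 reads against 1825547 to 4259789 for replicate 2. The third principal component (12.9% of variance) correlated with the number (r 0.719). Relations are therefore also given within each number. Each number holds 1 sample per group, so the contrasts were not tested within a number, and their directions are given instead. These directions use the libraries that made the calls. For named miRNAs, whose libraries do not overlap, the direction is fixed in advance and adds no support. The same largely holds for directions kept under omissions.

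The pipeline was tested on simulated data with 40 changed miRNAs in each of 3 runs. With 2 against 2 replicates it found 0% of 4-fold, 20% of 16-fold and 81.7% of 64-fold changes. With 2 against 6 it found 6.67, 62.5 and 90% of them. Small changes were thus mostly out of reach of the comparisons of 2 against 2.

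Alternatives covered other scalings, DESeq2, no filter, length variants of the miRNAs, other ways to treat repeat libraries, the replicate number as a block, fits on the groups of a contrast alone and the omission of each replicate. Added after seeing the data were runs without the 6 libraries above 70% ribosomal RNA, without repeat 1 of flower stage 12, with reads outside ribosomal RNA as the base of the 24-nt share, and without the 5 groups highest in miR156 and miR157.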

Results

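Small RNAs of 18 to 28 nt were sequenced from 27 organs and developmental stages of wild-type Columbia plants of Arabidopsis thaliana. The groups covered siliques 2, 3, 5 and 7 days old, juvenile, adult and cauline leaves, hypocotyl, cotyledon, whole seedling, root, shoot apical meristem (SAM), inflorescence, stem at the first node, 4 flower stages, the 4 floral organs of stage 12, stage 13 carpels, 2 embryo stages and imbibed seed. Hypocotyl, cotyledon, seedling, root and SAM came from plants 7 days old. The other groups, except seed, came from plants 4 to 7 weeks old. Each group had 2 biological replicates. Replicate 1 of some groups was sequenced in repeat libraries, which made 59 libraries for 54 replicates. The libraries held 1825547 to 6412670 reads. Reads identical to an annotated mature miRNA numbered 53472 to 691329 per replicate, with a median of 209589. Of 350 distinct mature sequences 323 were seen. A share of a library's reads had a 95% Wilson interval of at most ± 0.0723 points. These intervals and all counting intervals below cover counting error and nothing else. Levels are mean CPM (edgeR's read counts scaled to a common library size by TMM factors) ± SD of the 2 replicates of a group unless stated otherwise. In stage 12 stamen the scaled level of miR167a-5p exceeds the total that CPM refers to, while its plain share of miRNA reads there was 65.4% ± 10.5. P-values measure the spread between these samples, since the labels do not say that the replicates came from separate cultures.

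Fragments of ribosomal RNA made up 13.0 to 78.0% of the reads of a library and miRNAs 1.06 to 19.1%. The 6 libraries with more than 70% ribosomal RNA were replicate 1 of stage 12 sepal, of stage 12 stamen and of stages 10 to 11, both repeats of seedling replicate 1, and cotyledon replicate 2. Replicates 1 and 2 of a group correlated across the tested miRNAs with a median Pearson r of 0.887 (0.756 to 0.953, 32 pairs of libraries). Repeat libraries of replicate 1 correlated with a median r of 0.949 (0.931 to 0.989, 7 pairs). No pair agreed within sampling noise, since the lowest chi-square per degree of freedom was 6.96. MiRNAs are not independent replicates, so these correlations across miRNAs carry no p-value.

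MiR167a-5p, which targets the auxin response factors ARF6 and ARF8, had the highest mean level over all groups (244603 CPM, 21.1% of the reads of tested miRNAs). It was highest in stage 12 stamen, at 1058880 ± 738024 CPM, and stood at 7455 CPM in root. MiR159a, a regulator of GAMYB-like factors, came next at 182292 CPM and had its highest scaled level in juvenile leaf, at 462520 ± 99036 CPM. As a plain share of miRNA reads it was higher in siliques of day 3 (29.7%) and hypocotyl (29.1%) than in juvenile leaf (23.1%), and it did not pass the test across the groups (adjusted p 0.736). MiR159b-3p was also highest in juvenile leaf, at 340591 CPM. Other miRNAs among the 10 most abundant were miR161.1 (88198 CPM), which targets pentatricopeptide repeat transcripts, miR824-5p (67987 CPM), which targets AGL16, and miR167d (36481 CPM). MiR824-5p had a mean of 232604 CPM in root with an SD of 272419 CPM, so that mean rested on 1 replicate. Its mean log2 level was highest in green leaf embryo. MiR167d ran from 13.2 ± 5.09 CPM in stage 12 carpel to 466378 ± 592335 CPM in adult leaf 2, with an SD above the mean. MiR163, which targets methyltransferases, had its highest mean in adult leaf 1 (188067 ± 243283 CPM), which rested on 1 replicate. By mean log2 level it was highest in juvenile leaf. It was lowest in green leaf embryo (106 CPM). MiR319a, a regulator of TCP factors, was highest in the stem at the first node (215881 ± 116853 CPM) and lowest in cotyledon (639.8 CPM). MiR396b-5p, a regulator of GRF factors, was highest in siliques of day 5 (57327 CPM). MiR168a-5p, which targets AGO1, had its highest scaled level in juvenile leaf (63768 CPM), while its plain share was 3.19% there and 4.95% in flower stage 9, and it did not pass the test across the groups (adjusted p 0.722).

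Across all 27 groups, 146 of the 216 tested miRNAs differed at an adjusted p below 0.05. Enrichment in a group, meaning a difference from the mean log2 level of the other 26 with an estimate of at least 4-fold, was called 771 times. In simulated data this enrichment test made 12 false calls beside 40 true ones, so some of the 771 are false. The number per group ran from 14 in stage 12 sepal to 42 in siliques of day 5, siliques of day 7 and flower stages 10 to 11. Leaves and cotyledon shared miR3932a among their most enriched miRNAs, with a log2 ratio of 7.78 in juvenile leaf, 6.17 in adult leaf 1, 9.13 in adult leaf 2, 7.74 in cauline leaf and 6.6 in cotyledon. The miR3932 family stood at 2788 ± 3749 CPM in adult leaf 2, an SD above the mean, and at 0 CPM in siliques of day 2. MiR867, miR780.1 and miR780.2 led the inflorescence, stamen and flower stages 10 to 11 and 12, with miR867 at 21270 ± 1744 CPM in stage 12. MiR771 led both carpel groups and flower stage 13, and reached 20644 ± 876 CPM in stage 13 carpel. MiR156a-3p and miR156c-3p led green leaf embryo at 28129 ± 925 and 18494 ± 410 CPM. These SDs compare the summed repeats of replicate 1 with replicate 2, while the 4 single libraries ran from 1761 to 46979 CPM for miR156a-3p and from 1145 to 30552 CPM for miR156c-3p. MiR156c-3p also led seed, with a log2 ratio of 7.07. MiR5650 led root, hypocotyl and seedling, with log2 ratios of 6.44, 5.40 and 5.04. Group means of log2 CPM (prior count 2, which damps low levels) spanned 3.93 for miR5650 and 6.44 for miR3932a. Most ratios of these miRNAs exceed the spans, so their size depends on groups with few or 0 reads. In SAM the leading miRNA was miR173-5p, the trigger of TAS1 and TAS2 small RNAs, at 162386 ± 224665 CPM. Its log2 ratio to the other groups was -1.17 when SAM replicate 2 was left out. MiR856 in flower stage 9 behaved alike, at -1.17 without that group's replicate 1. Both miRNAs also differed with the replicate number across the groups. MiR856 averaged 40.8 CPM in replicate 1 and 0 CPM in replicate 2, so replicate 1 alone could carry its call. MiR173-5p averaged 1632 CPM in replicate 1 and 35342 CPM in replicate 2, and was higher in replicate 2 in 24 groups. DESeq2 called 423 enrichments.

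Leaves of different phases were compared because miR156 and miR157, which repress SPL factors, mark the juvenile phase and miR172, which represses AP2-like factors, the adult phase. In cauline leaves miR172a, processed from chromosome 2 at 11942918 to 11942938 and from a second locus, stood at 49653 ± 52607 CPM, against 1995 ± 367 CPM in juvenile leaves. It did not pass the test over all miRNAs (log2 fold change 4.64, adjusted p 0.263). As a group, the 5 tested members of the miR172 list were higher in cauline than in juvenile leaf (median log2 fold change 4.64, also with members read at 0 set to their bound, adjusted p 0.028). Among these 5, miR172b-5p and miR172d-5p are -5p partner strands. None of the 5 was called over all 216 miRNAs and 3 were when adjusted over the list alone, among them miR172b-5p (4.99) and miR172c (9.49 as fitted, with 0 reads in juvenile leaf and 412 ± 523 CPM in cauline leaf). This group call ended without cauline leaf replicate 1 (adjusted p 0.0668) or 2 (0.162), without juvenile leaf replicate 1 (0.188) or 2 (0.158), and in 25 of the 40 single-replicate omissions run, over which the adjusted p ran from 0.0226 to 0.188. In adult leaves (4 replicates) miR172a stood at 21556 ± 32987 CPM and did not pass the test (log2 fold change 2.81, adjusted p 0.56). MiR156a-5p was measured at 2401 ± 1829 CPM in juvenile, 5806 ± 4847 CPM in adult and 3285 ± 1576 CPM in cauline leaves. MiR157a-5p was measured at 15960 ± 15246, 20288 ± 3855 and 9300.4 ± 5620.0 CPM in the same order. No single miRNA was called by edgeR between adult and juvenile leaf (16 at an unadjusted p below 0.05, 0 by DESeq2) or between cauline and juvenile leaf (20 unadjusted, 5 by DESeq2) in the model without a term for the replicate number. For cauline leaf edgeR called 1 with DESeq2 size factors and 1 without a filter on low counts, and for adult leaf 1 with every library as a replicate. Without juvenile leaf replicate 2 the counts were 8 and 2. MiR866-3p had the lowest adjusted p of a list member in the cauline comparison, with a log2 fold change of -5.87 (adjusted p 0.0523, or 0.0119 adjusted over the list alone).

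Siliques of day 7 were compared with day 2 to follow the maturing fruit. The 4 miRNAs called were all higher at day 7, and 3 of them came from miR156 precursors. MiR156a-3p, from chromosome 2 at 10676470 to 10676491, had 423 reads at day 7 and 0 at day 2, which made it at least 76.3-fold higher (adjusted p 0.00589). MiR156c-3p, from chromosome 4 at 15415426 to 15415447, rose from 4.54 ± 6.42 to 1094 ± 1306 CPM, a ratio of 163 with a counting interval of 45 to 1351 (adjusted p 0.0154). MiR156a-5p, made at 6 loci, rose from 396 ± 97.2 to 10385 ± 10107 CPM (log2 fold change 4.71, SE 1.2, adjusted p 0.0213). MiR826a, which targets AOP2 and responds to nitrogen starvation, rose from 2.27 ± 3.21 to 2894 ± 2674 CPM, a ratio of 901 with a counting interval of 161.4 to 35595 (adjusted p 0.0154). It lies on chromosome 4 at 1340528 to 1340548. The SPL list thus had 3 of 13 members higher, also when adjusted over the list alone. Of these, the 2 -3p arms are not themselves the strand known to repress SPL transcripts, and the list as a whole did not pass (adjusted p 0.116). Each of the 4 calls ended when day 2 replicate 1, day 2 replicate 2 or day 7 replicate 2 was left out, with adjusted p values up to 0.408 for miR156a-5p, and a fit on the 2 silique groups compared alone called 0. DESeq2 called 8 higher and 3 lower. All 4 calls were higher at day 7 within replicate 1 and within replicate 2, each with 1 sample per group. Libraries that do not overlap fix this direction in advance, so it adds no support.

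**Figure D1:**
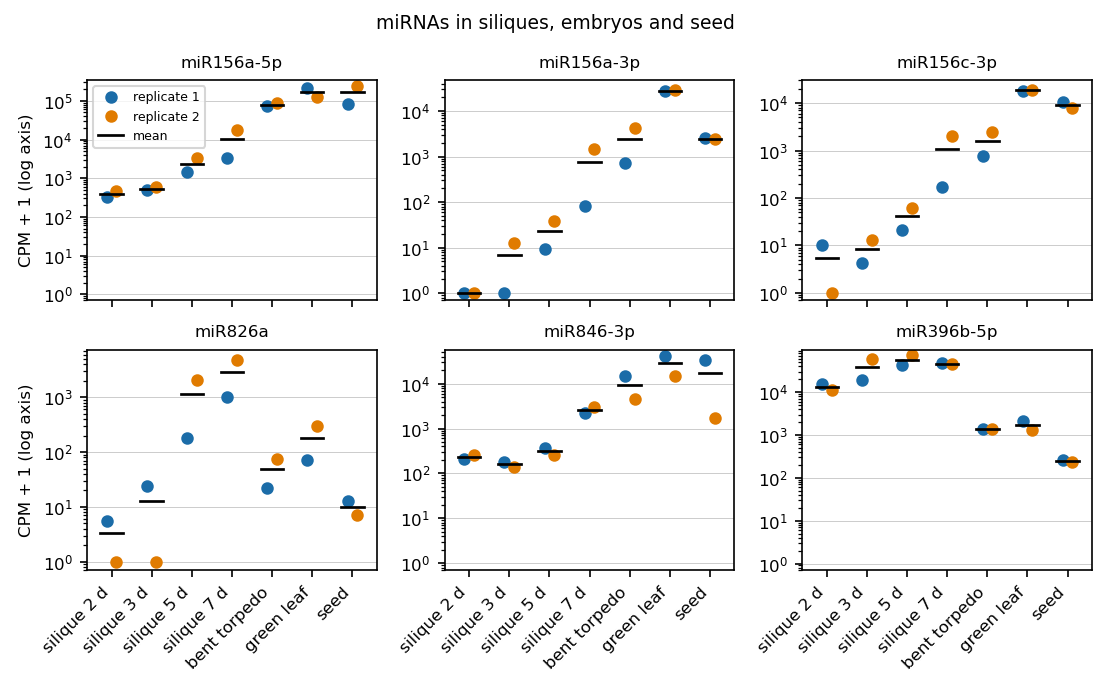
Levels of 6 miRNAs in siliques of 4 ages, 2 embryo stages and seed, as CPM + 1 on a log axis, with one point per replicate and a bar at the mean of both. MiR156a-3p had 0 reads at day 2, 777 ± 983 CPM at day 7 and 28129 ± 925 CPM in green leaf embryo.

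The green leaf embryo was compared with the younger bent torpedo embryo. MiR156a-5p stood at 166164 ± 62081 CPM in green leaf and 80360 ± 9139 CPM in bent torpedo embryos. MiR156a-3p stood at 28129 ± 925 against 2437 ± 2449 CPM, and miR156c-3p at 18494 ± 410 against 1602 ± 1187 CPM. These differences did not pass the test (adjusted p 0.91 for miR156a-5p and 0.513 for miR156a-3p). No miRNA was called by edgeR, 13 had an unadjusted p below 0.05 and DESeq2 called 1.

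Flowers of stage 13 (open) were compared with stage 9 (young buds). Of 6 miRNAs called, 2 were higher and 4 lower at stage 13. MiR780.1 and miR780.2, which lie side by side on chromosome 4 from 8504145 to 8504186, were the most reduced. MiR780.1 fell from 8193 ± 10138 to 3.41 ± 1.26 CPM, a ratio of 1684 with a counting interval of 465 to 13921 (adjusted p 0.0047). MiR780.2 fell from 3787 ± 3215 to 1.26 ± 1.78 CPM, a ratio of 1816 with a counting interval of 325 to 71827 (adjusted p 0.00322). MiR867 (log2 fold change -6.78, adjusted p 0.0407) and miR839-5p (-5.97, adjusted p 0.0134) also fell. MiR771, from chromosome 3 at 19659381 to 19659402, rose from 147 ± 208 to 17855 ± 8983 CPM (log2 fold change 6.88, SE 1.9, adjusted p 0.0409). MiR156h rose from 13.1 ± 18.5 to 566 ± 312 CPM (log2 fold change 5.14, SE 1.5, adjusted p 0.044). Among the lists, 3 of 49 Brassicaceae-restricted miRNAs and 1 of 13 SPL regulators were called over all miRNAs, and 4 and 3 when adjusted over the list alone. With DESeq2 size factors 0 were higher and 4 lower, with all deposited reads as library size 3 and 2, with DESeq2 7 and 6, and no call remained without stage 13 replicate 1 or replicate 2 or more than 1 without stage 9 replicate 2. The call of miR156h ended in 4 of 4 omissions. All 6 calls kept their direction within both replicate numbers, each with 1 sample per group. Libraries that do not overlap fix this direction in advance.

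Each floral organ of stage 12 was set against the mean of the other 3 (2 against 6 replicates), which asks where in the flower a miRNA accumulates. In stamen 37 miRNAs were higher and 1 lower (28 and 3 by DESeq2). MiR780.2 was at 1369 ± 218 CPM in stamen and 6.17 ± 6.54 CPM in the other organs (log2 fold change 8.02, SE 1.2, adjusted p 1.18e-05). MiR867, from chromosome 4 at 11375387 to 11375407, was at 13882 ± 4908 against 127 ± 105 CPM (6.90, SE 1.1, adjusted p 1.94e-05). MiR845a and miR845b, which act on retrotransposons in pollen, lie at 12217457 to 12217477 and 12214086 to 12214107 of chromosome 4. MiR845a was at 7150.0 ± 5860.3 against 92.2 ± 76.6 CPM (6.44, SE 1.0, adjusted p 1.18e-05) and miR845b at 1411 ± 1723 against 24.2 ± 38.2 CPM (6.45, SE 1.1, adjusted p 2.74e-05). The pollen marker list thus had 2 of 2 members higher, also when adjusted over the list alone (list adjusted p 0.000158). Other miRNAs with large rises were miR869.2 (7.24), miR780.1 (6.92), miR5020b (6.45), miR866-3p (6.08) and, from few reads, miR774a, with a ratio of 154 (counting interval 25.6 to 6280), and miR5017-3p, with a ratio of 77.0 (11.8 to 3240). MiR159b-3p was the one miRNA that was lower, at 11763 ± 7126 against 110287 ± 65454 CPM (-3.09, SE 0.96, adjusted p 0.021).

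The SPL regulators were higher in stamen as a group (median log2 fold change 2.78, or 2.23 with members read at 0 set to their bound, adjusted p 2.30e-05). Of 13 members 5 were called over all miRNAs and 6 when adjusted over the list alone, led by miR156a-5p (4.86), miR157a-5p (4.27) and miR157d (3.89). With all deposited reads as library size the median was 2.04. The list also passed a test for change in either direction (adjusted p 0.00205), which ended with all reads as library size (0.108), without petal replicate 1 (0.0845), stamen replicate 1 (0.147), carpel replicate 1 (0.0598) or petal replicate 2 (0.116), and without the 6 libraries above 70% ribosomal RNA (0.0936). MiR167a-5p was called higher in stamen (4.46, adjusted p 0.000318) as 1 of 14 members of the auxin response list, also when adjusted over the list alone. Phosphate-linked miR399a (4.68) and miR399d (5.15) were 2 of 9 members called (3 when adjusted over the list alone), and NF-YA regulators miR169a-5p (2.32) and miR169h (2.95) were 2 of 7, also when adjusted over the list alone. The Brassicaceae-restricted list changed in either direction (adjusted p 0.000269) with 9 of 49 members higher, also when adjusted over the list alone. Over all 216 tested miRNAs 37 were higher, a like share, and the median log2 fold change was 0.425. The list's directional test depended on the scaling (adjusted p 0.0604 with TMM, 0.0251 with DESeq2 size factors and 0.444 with all deposited reads as library size). The list's median of 0.273 (0.485 with members at their bound) turned to -0.157 with all deposited reads as library size. The change in either direction ended without the 6 libraries above 70% ribosomal RNA (adjusted p 0.136), sepal replicate 1 (0.0721), petal replicate 1 (0.0845), stamen replicate 1 (0.0947), carpel replicate 1 (0.0598), petal replicate 2 (0.116) or carpel replicate 2 (0.0801). Stamen replicate 1 held 72.7% ribosomal RNA and replicate 2 held 28.1%. The count of 38 became 22 without the 6 libraries above 70%, 21 in a fit on the 4 organs alone, 20 without stamen replicate 1, 25 without stamen replicate 2, 23 without sepal replicate 1 or 2 and 24 without petal replicate 1. The calls of miR845b (adjusted p 0.182) and miR159b-3p (0.146) ended without stamen replicate 1 and that of miR5017-3p in 6 of 8 omissions (up to 0.692). Within the replicate numbers 36 of the 38 had the same direction in both, in the libraries that made the calls.

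In carpels of stage 12, 8 miRNAs were called higher and 2 lower, whereas DESeq2 called 15 higher and 18 lower, so the balance of directions was not stable. MiR771 was at 16741 ± 5593 CPM, against 50.4 ± 34.1 CPM in the other organs (log2 fold change 8.44, SE 1.3, adjusted p 1.28e-05). MiR851-5p and miR851-3p, from the same stretch of chromosome 3 (miR851-5p at 19659646 to 19659666), were higher as well. MiR851-5p stood at 296 ± 22.5 against 5.77 ± 11.1 CPM (6.39, adjusted p 0.000516), and miR851-3p had 41 reads in carpel and 0 elsewhere, which made it at least 30.5-fold higher (adjusted p 0.000516). MiR3933 was at 631 ± 404 against 5.61 ± 6.37 CPM (6.68, adjusted p 0.000321) and miR156h at 1135 ± 93.0 against 75.9 ± 88.5 CPM (4.58, adjusted p 0.000516). MiR159b-5p (2.99) and miR172d-5p (3.48) were also higher, and both are -5p partner strands. The lower miRNAs were the star strands miR396a-3p (-4.36, adjusted p 0.0257) and miR396b-3p (-3.76, adjusted p 0.0218), 2 of 6 members of the TCP and GRF list, also when adjusted over the list alone. The SPL list changed in either direction in carpel (adjusted p 0.0155), with miR156h higher over all miRNAs and 1 higher and 4 lower when adjusted over the list alone. Its median was -2.37, or -2.11 with members at their bound. The Brassicaceae-restricted list also changed in either direction (adjusted p 0.0155), with 3 of 49 members higher over all miRNAs, 5 when adjusted over the list alone, a median of 0.00348 (0.0598 with members at their bound) and a mean of -0.178, which differ in sign. Neither list change held without the 6 libraries above 70% ribosomal RNA (adjusted p 0.101 and 0.0936), the SPL change ended with all deposited reads as library size (0.108), and each omission of a floral organ library of stage 12 ended the Brassicaceae-restricted change (adjusted p 0.0721 to 0.432, highest without carpel replicate 1) and, except for sepal replicate 2, the SPL change (0.0569 to 0.475). The count of 10 fell to 6 without petal replicate 1 or carpel replicate 1. Single omissions ended the calls of miR159b-5p (3 of 8), miR396a-3p (5 of 8) and miR396b-3p (3 of 8). In the libraries that made the calls, 9 of 10 calls had the same direction in both replicate numbers.

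In sepals of stage 12, 5 miRNAs were higher and 0 lower. MiR167d, from chromosome 1 at 11137556 to 11137577, was at 9801 ± 9066 CPM, against 60.9 ± 62.2 CPM elsewhere (log2 fold change 7.94, SE 1.3, adjusted p 9.04e-05). Both arms of miR164c, a regulator of NAC boundary genes, were higher and were 2 of 11 members of the polarity and boundary list, also when adjusted over the list alone. MiR164c-5p stood at 1265 ± 526.4 against 116 ± 96.5 CPM (3.52, adjusted p 0.0211), and miR164c-3p had a ratio of 76.2 (counting interval 12.3 to 3153, adjusted p 0.0211). MiR843 had a ratio of 16.9 (4.73 to 91.9, adjusted p 0.0261). The remaining call, miR172e-3p (4.30, adjusted p 0.0211), had overlapping libraries and is named as a member of the AP2 list. In petals miR390b-3p, whose partner strand triggers TAS3 small RNAs, was the 1 miRNA called, at 1937 ± 637 against 109 ± 148 CPM (4.81, SE 1.2, adjusted p 0.0425). The sepal count was 0 without the 6 libraries above 70% ribosomal RNA, 3 with all reads as library size, 1 without stamen or carpel replicate 1, 2 without petal replicate 1, petal replicate 2 or sepal replicate 2 and 3 without stamen replicate 2, while miR167d was called in 8 of 8 omissions. The calls of miR164c-3p, miR843 and miR164c-5p ended in 6, 6 and 7 of 8 omissions (adjusted p up to 0.199). DESeq2 called 13 higher and 6 lower in sepal and 1 higher and 4 lower in petal. The petal call ended in 8 of 8 omissions and in a fit on the 4 organs alone (0 calls). All 6 calls had the same direction in both replicate numbers, in the libraries that made the calls.

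**Figure D2:**
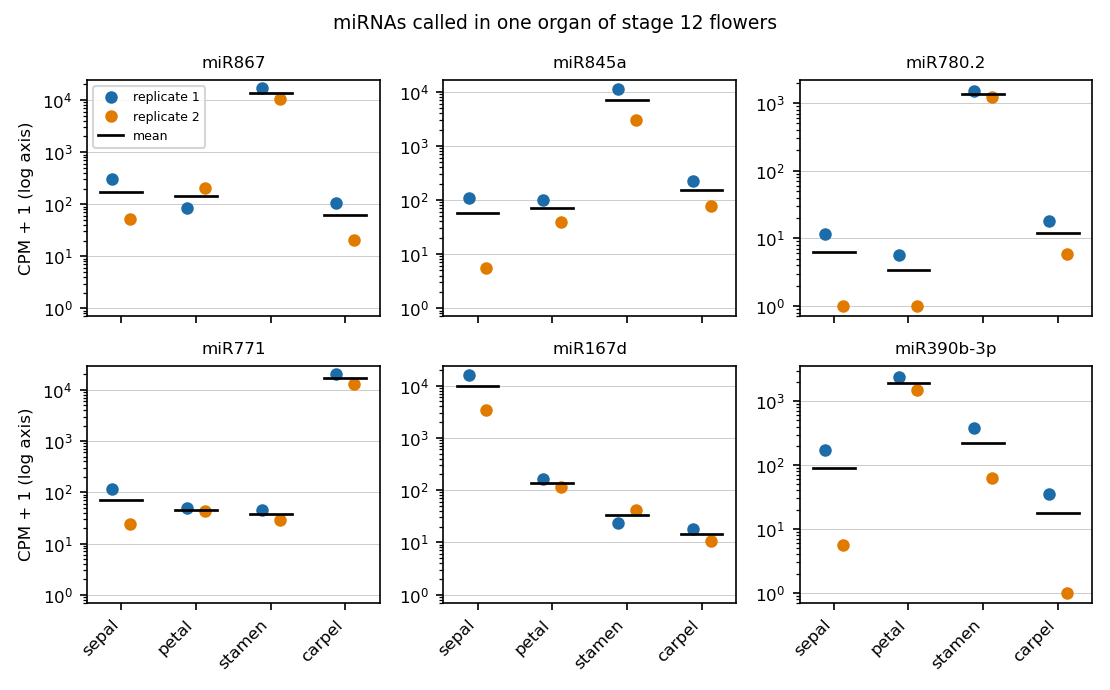
Levels of 6 miRNAs in the 4 organs of stage 12 flowers, as CPM + 1 on a log axis, with one point per replicate and a bar at the mean of both. MiR867, miR845a and miR780.2 were highest in stamen, miR771 in carpel (16741 ± 5593 CPM), miR167d in sepal and miR390b-3p in petal.

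Carpels of stage 13 were compared with carpels of stage 12, and the change was set against that of whole flowers. MiR771 stayed abundant, at 20644 ± 876 CPM in stage 13 carpels. No miRNA was called by edgeR between the carpel stages (3 at an unadjusted p below 0.05, 1 by DESeq2) or for the difference between carpel and whole flower (11 unadjusted, 1 by DESeq2). Flower stage 12 replicate 2 held miR167a-5p at 1064084 CPM, against 50915 to 154697 CPM in the 3 repeats of replicate 1.

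Root was compared with the mean of hypocotyl, cotyledon and SAM, all from plants 7 days old (2 against 6 replicates). There were 15 miRNAs higher and 11 lower in root. MiR846-3p and miR842, which lie in one transcription unit on chromosome 1 (22577662 to 22577682 and 22577194 to 22577214) and target jacalin lectins, were at 12093 ± 1235 against 2252 ± 3006 CPM (log2 fold change 3.18, SE 0.79, adjusted p 0.00499) and at 1046 ± 902 against 57.6 ± 45.2 CPM (4.54, SE 1.0, adjusted p 0.00302). Members of the auxin response list moved both ways, with 4 of 14 called (5 when adjusted over the list alone). MiR167c-3p was at 780 ± 213 against 39.3 ± 50.5 CPM (4.89, adjusted p 0.000987) and miR167c-5p, from chromosome 3 at 1306750 to 1306770, at 1973 ± 934 against 155.7 ± 200.5 CPM (4.79, adjusted p 0.00302). MiR167d was lower, at 604 ± 277 against 53450 ± 54415 CPM (-6.00, adjusted p 0.0263), and so was miR167a-3p (-5.31, adjusted p 0.0177). MiR828, which targets MYB transcripts and TAS4, had 0 reads in root and 132 in the other organs, at least 24.3-fold lower (adjusted p 0.00302). Of the GRAS list, miR170-3p (ratio 48.6, counting interval 16.5 to 237), its partner strand miR170-5p (-4.69) and miR171a-3p (-5.17) were lower. These were 3 of 6 members, also when adjusted over the list alone, while the list as a whole did not pass (adjusted p 0.13). MiR172c (6.89) and miR172e-3p (4.83) were higher, 2 of 5 AP2 regulators (3 when adjusted over the list alone). MiR156a-3p (-5.30) and miR157c-3p (ratio 129, counting interval 35.6 to 1071) were lower, 2 of 13 SPL regulators, and both are -3p strands. Adjusted over the list alone 5 SPL regulators were lower and 1, miR156f-3p, was higher (3.04). MiR399c-5p (3.62), miR8182 (4.49) and miR5019 (3.40) were also higher, and miR1888a (ratio 183, counting interval 32.6 to 7248) and miR5026 (-5.40) lower. Of 49 Brassicaceae-restricted miRNAs 5 were higher, among them miR842, miR846-3p and miR837-5p (4.43), and 0 lower.

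With DESeq2 size factors 27 miRNAs were higher and 11 lower in root, and with all deposited reads as library size 27 and 10. Without root replicate 2 the count was 5, and the calls of miR828 (adjusted p 0.077), miR1888a (0.164), miR5026 (0.0887), miR171a-3p (0.257) and miR170-5p (0.125) ended. Those of miR8182, miR399c-5p, miR5019, miR156a-3p, miR157c-3p, miR167d and miR170-3p ended in 3, 5, 2, 2, 5, 7 and 6 of 8 omissions. Those of miR167c-3p, miR167c-5p, miR842 and miR846-3p held in 8 of 8 omissions. In the libraries that made the calls, 26 of 26 had the same direction in both replicate numbers.

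The SAM was compared with hypocotyl and cotyledon (2 against 4 replicates) for the same phase regulators. MiR156a-5p stood at 11900.2 ± 2178.1 CPM in SAM and 43734 ± 30548 CPM in the other organs (log2 fold change -1.88, adjusted p 0.657). MiR157a-5p stood at 30511 ± 7137 against 61892 ± 34237 CPM, and miR172a at 8353 ± 9791 against 1262 ± 1673 CPM (3.34, adjusted p 0.609). The SPL list as a group was lower in SAM (median -1.88, or -1.85 with members read at 0 at their bound, adjusted p 0.028), although 0 of 13 members were called over all miRNAs and 0 when adjusted over the list alone. The list call ended without cotyledon replicate 2 (adjusted p 0.125), SAM replicate 1 (0.114), SAM replicate 2 (0.0528) or stamen replicate 1 (0.0506). No single miRNA was called by edgeR (13 at an unadjusted p below 0.05, 1 by DESeq2).

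Of 15 lists fixed beforehand, tested in 13 comparisons with edgeR's fry, 4 list and comparison pairs passed on balance in one direction and 4 in either direction, as given above. With all deposited reads as library size 10 passed in one direction, and without the 6 libraries above 70% ribosomal RNA 0 passed in either direction. Neither test compares a list with other miRNAs. With TMM scaling the other 12 lists passed in no single direction. Their lowest adjusted p values were 0.266 for the auxin response regulators, 0.108 for polarity and boundary, 0.103 for TCP and GRF, 0.197 for MYB, 0.108 for phosphate, 0.574 for sulfate, 0.238 for copper, 0.199 for NF-YA, 0.13 for GRAS, 0.444 for silencing feedback, 0.164 for secondary siRNA triggers and 0.0604 for the Brassicaceae-restricted miRNAs. Calls of single members, summed over the comparisons, numbered 12 for SPL, 5 for AP2, 7 for auxin response, 2 for polarity and boundary, 2 for TCP and GRF, 3 for MYB, 3 for phosphate, 0 for sulfate, 1 for copper, 3 for NF-YA, 3 for GRAS, 0 for silencing feedback, 1 for secondary siRNA triggers, 21 for Brassicaceae-restricted and 2 for the pollen marker. Adjusted over the list alone they numbered 23, 14, 17, 3, 3, 5, 7, 0, 1, 4, 4, 0, 2, 30 and 6 in the same order. The copper call was miR397a in stamen (3.76, adjusted p 0.035) and the siRNA trigger call miR400 in stamen (2.85, adjusted p 0.0169).

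Across the 27 groups, the summed level of miR156 and miR157 and that of miR172 ran in opposite directions. Green leaf embryo held 217155 ± 59739 CPM of miR156 and miR157 and 491 ± 565 CPM of miR172, while cauline leaf held 13956 ± 7768 and 50712 ± 53253 CPM. Petal held the lowest level of miR156 and miR157, 1965 CPM, with 4184 CPM of miR172. Pearson's r of the log2 levels was -0.655 (permutation p 0.0002, adjusted over 2 relations 0.0004) and Spearman's rho -0.534 (permutation p 0.00462). The permutations take the groups as independent. Whole flowers and seedlings hold organs measured as other groups, and silique and embryo stages follow one another, so these p-values may be too small. Without green leaf embryo and seed, the 2 groups farthest from the median, r was -0.535 (permutation p 0.00522). Without the 5 groups with most miR156 and miR157 (green leaf embryo, seed, hypocotyl, cotyledon and bent torpedo embryo), a subset chosen after seeing the plot, r over the other 22 groups was -0.267 (permutation p 0.232), and leaving out extreme groups narrows the range and by itself lowers r. Within replicate 1 r was -0.686 (permutation p 8.00e-05) and within replicate 2 it was -0.50 (permutation p 0.0079).

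**Figure D3:**
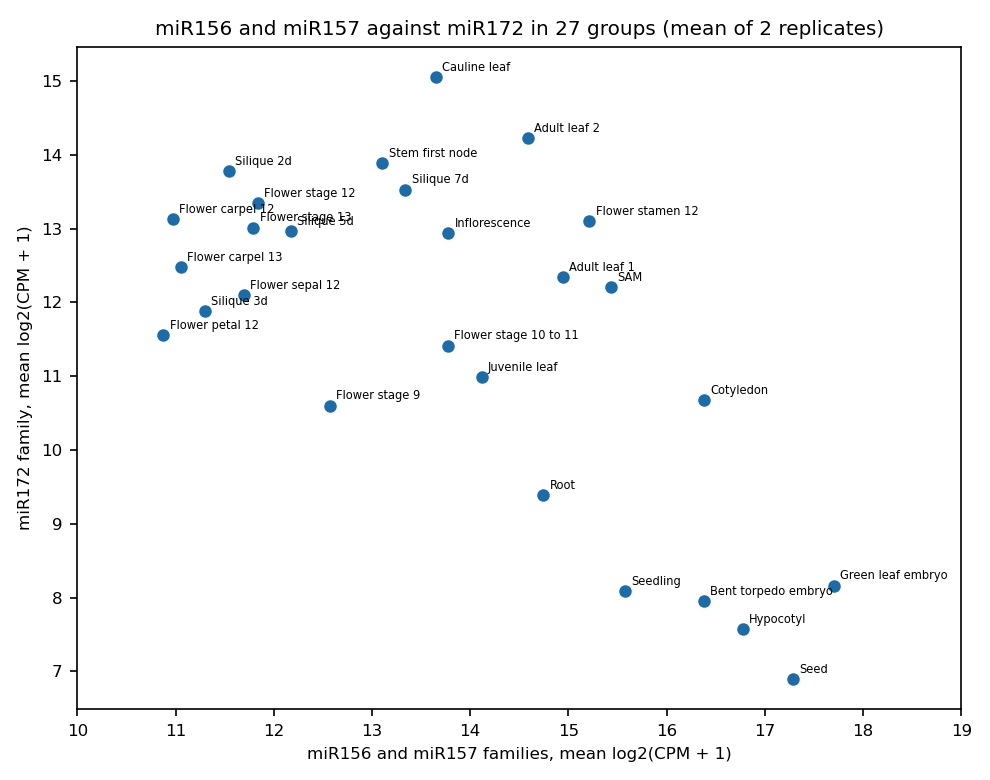
Mean log2(CPM + 1) of the miR172 family against that of the miR156 and miR157 families, with one point per group as the mean of 2 replicates. Pearson's r was -0.655 over the 27 groups and -0.267 without the 5 groups highest in miR156 and miR157.

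Small RNAs of 24 nt, the size class of heterochromatic siRNAs, made up a mean of 40.5% (SD 4.91) of the reads in the 7 silique, embryo and seed groups and 29.3% (SD 11.6) in the 20 others. The difference of 11.2 points had an exact two-sided permutation p of 0.0221 (19618 of 888030 splits of the groups, 0.0221 adjusted over 2 relations). This test too takes related groups as independent, so its p may be too small. The highest shares lay outside these 7 groups, in stage 13 carpels (51.9%), stage 13 flowers (51.0%) and stage 12 carpels (48.7%), and the lowest in cotyledon (15.8%) and seedling (16.2%). The ribosomal RNA share differed between the same sets of groups, at 29.8% (SD 8.94) against 47.9% (SD 15.3). Among reads outside ribosomal RNA, a measure chosen after seeing the data, the 24-nt difference was 8.98 points (53.9 against 44.9%, exact permutation p 0.0628). It was 8.17 points within replicate 1 (exact permutation p 0.113), 14.2 points within replicate 2 (exact permutation p 0.00713), 2.03 points when each distinct sequence counted once (exact permutation p 0.363), and without bent torpedo embryo replicate 2 the exact permutation p was 0.0503.

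**Figure D4:**
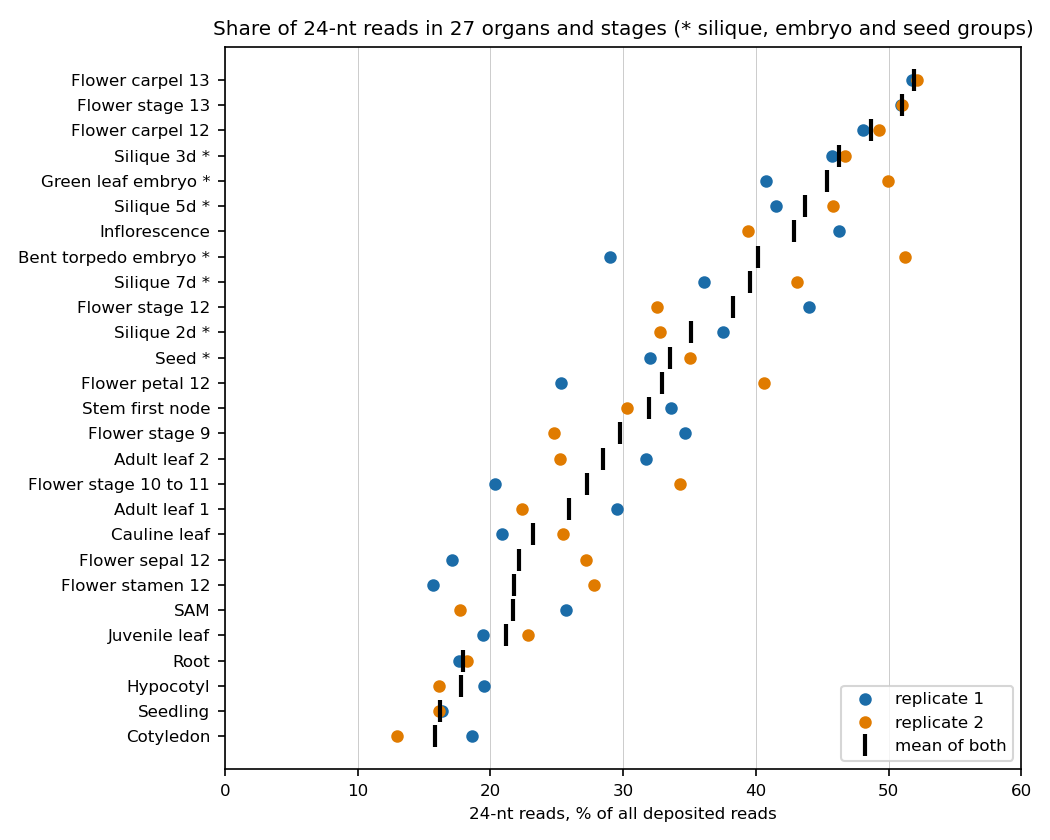
Share of 24-nt reads among all deposited reads in 27 groups, with one point per replicate and a tick at the mean of both. The 7 silique, embryo and seed groups, marked with an asterisk, averaged 40.5% and the other 20 averaged 29.3%.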

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

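The comparison of replicates by ribosomal RNA content and both tests on the repeats of flower stage 12 were chosen after the result was seen, as were the comparison of single silique levels with embryo levels and the overlap after thinning; the other tests here were not.

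Flower stage 12 replicate 2 stood far from the 3 repeat libraries of replicate 1 in 3 of 17 measures. The 1 in 20 that chance gives for exchangeable libraries does not apply here, since 3 of the 4 libraries are repeats of 1 replicate and a difference between replicates is set against technical spread. MiR167a-5p reached 1064084 CPM there against 50915 to 154697 CPM in the repeats, with a gap of 0.898 of the whole range. MiR167d reached 21463 against 571 to 2758 CPM (gap 0.895), and miR163 reached 33595 against 5664 to 8814 CPM (gap 0.887). MiR163 was also higher in replicate 2 in 23 groups. The critical value for 4 libraries is 0.829. In green leaf embryo 0 of 17 measures stood apart.

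Levels of 103 of 216 miRNAs differed between libraries numbered replicate 1 and replicate 2 across the groups. Lower depth of replicate 2 was argued against, since 87 miRNAs differed after every replicate was thinned to 53472 miRNA reads, 84.5% of the 103 before, and 78 differed in both runs with the same direction in 78 of them. A higher ribosomal RNA content of replicate 1 was argued against too, since 9 of 9 groups without such an excess showed the same pattern, with correlations of 0.503 to 0.74 with the other groups. Library preparation that favours some end sequences stays open and may contribute, since the first 2 and last 2 bases accounted for 11.2% of the variance of the difference (permutation p 0.0181, shuffle median 5.3%, 10000 shuffles). That leaves most of the difference without a tested explanation, and no biological explanation was tested.

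Repeat 1 of flower stage 12 replicate 1 held 61.2% ribosomal RNA, against 18.84 and 20.24% in the other repeats, and 25.2% 24-nt reads against 51.2 and 50.2%. Dilution by ribosomal RNA alone was argued against, since its miRNA counts differed from the nearer repeat 9.33 times as much (chi-square per degree of freedom) as those repeats differed from each other. A different library batch could account for it and stays open. The difference of repeat 1 from the other repeats correlated across 216 miRNAs with the like difference in green leaf embryo (r 0.387), and miRNAs are not independent replicates. No biological explanation was tested, since the repeats share one replicate.

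MiR156 members were higher in siliques of day 7 than of day 2. Scaling by a few abundant miRNAs was argued against, since the median log2 fold change of the called members was 8.58 with all deposited reads as library size and 7.58 with TMM. Embryo tissue inside the older siliques stays open and may supply part of these reads, since 8 of 8 miRNAs enriched in both embryo groups and outside the family were higher at day 7, against 99 of 195 other miRNAs (one-sided Fisher's exact p 0.00524). That p takes miRNAs as independent, which they are not. MiR842, miR846-3p and miR846-5p, all among the 8, come from one transcription unit, and all folds rest on the same silique libraries. Embryos of the 2 stages measured would not alone supply miR826a, at 2894 CPM at day 7 against 47.2 CPM in bent torpedo and 181 CPM in green leaf embryo, miR845a (4958 against 1097 and 928 CPM) or miR5639-3p (1424 against 111 and 24.1 CPM), and younger embryos were not measured. A change of the silique's own tissues with age stays open as well and was not tested.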

How the results depend on the processing

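The runs without libraries above 70% ribosomal RNA, without repeat 1 of flower stage 12 with reads outside ribosomal RNA and without the 5 groups highest in miR156 and miR157 were chosen after seeing the data. Counts here are of called miRNAs unless named otherwise, and where a count changed the cause was not tested, beyond the fewer libraries that an omission or a fit on a contrast's groups alone leaves. Results not listed kept their side of the threshold within 1.5 times the main value. Where an omission left a group with 1 sample, it was taken to vary like the other groups.

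DESeq2 size factors gave 1 for cauline leaf and 4 for flower stages. All deposited reads as library size gave 9 for siliques, 3 for sepal, 6 for petal and 10 list and comparison pairs. DESeq2 gave 423 enrichments, 5 for cauline leaf, 11 for siliques, 13 for flower stages, 19 for sepal, 5 for petal, 33 for carpel and 1 each for carpel stages, their interaction, embryos and SAM. Without a filter there were 1 for cauline leaf, 2 for petal, 16 for carpel and 41 for root. Length variants gave 1 for cauline leaf and 44 for root. The first repeat alone gave 1 for cauline leaf. Every library as a replicate gave 1 for adult leaf, 1 for cauline leaf, 0 for petal and 15 for carpel. Fits on a contrast's groups alone gave 0 for siliques, 8 for sepal, 0 for petal and 21 for stamen. Without the 6 libraries above 70% ribosomal RNA there were 1 for cauline leaf, 4 for flower stages, 0 for sepal, 22 for stamen and 0 lists changed in either direction. The 24-nt difference was 2.03 points over distinct sequences, 8.98 outside ribosomal RNA and 8.17 within replicate 1. The correlation of miR156 and miR157 with miR172 was -0.587 with all reads and -0.726 for miR156 alone, and fell short of the threshold at -0.267 (permutation p 0.232) without the 5 groups highest in miR156 and miR157. Size factors shifted the median log2 fold change by -0.588 to 0.222 and all reads by -0.573 to 0.977, over 0.1 in 11 of 13 comparisons each. With all reads 4 of 4 silique, 4 of 6 flower, 3 of 5 sepal, 28 of 38 stamen, 9 of 10 carpel and 25 of 26 root calls were shared.

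With the replicate block there were 1 for adult leaf, 2 for cauline leaf, 12 for siliques, 22 for flower stages, 19 for sepal, 35 for carpel, 48 for root, 14 lists in one direction and 17 in either. Called higher and lower were 11 and 11 for flower stages, 15 and 4 for sepal, and 16 and 19 for carpel, where the balance turned. The results above rest on the model without this block. The samples were not treated as paired, since 27 of 351 pairs of groups had a correlation of replicate differences of 0.1 or less. However, 324 exceeded it (median 0.377, -0.158 to 0.726), and the block lowered the common dispersion from 0.771 to 0.501. Most groups thus shared a replicate effect, which the model without the block leaves in its spread. A comparison without a call in that model is therefore no evidence that nothing differs. Of 50 named contrast values 50 kept direction and call under the replicate block.

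Omitting each replicate in turn gave 143 to 152 miRNAs that differed among groups, 751 to 804 enrichments and, for the 24-nt share, 9.59 to 12.8 points. The correlation stayed between -0.685 and -0.601. Adult leaf gave 0 to 8 (8 without juvenile leaf replicate 2) and cauline leaf 0 to 2 (2 without the same). Siliques gave 0 to 4 (0 without day 2 replicate 1, day 2 replicate 2 or day 7 replicate 2). Flower stages gave 0 to 7 (0 without stage 13 replicate 1 or 2, 1 without stage 9 replicate 2). Sepal gave 1 to 4 (1 without stamen or carpel replicate 1, 2 without petal replicate 1 or 2 or sepal replicate 2, 3 without stamen replicate 2). Petal gave 0 in 8 of 8. Stamen gave 20 to 36 (20 without stamen replicate 1, 25 without stamen replicate 2, 23 without sepal replicate 1 or 2, 24 without petal replicate 1). Carpel gave 6 to 10 (6 without petal or carpel replicate 1). Root gave 5 to 30 (5 without root replicate 2). Carpel stages, their interaction, embryos and SAM gave 0 in each omission. Lists in one direction gave 2 to 8 (2 without stamen replicate 1, SAM replicate 1 or 2, 6 without juvenile leaf replicate 2, 8 without flower stage 12 replicate 2). Lists in either direction gave 0 to 7 (0 without petal replicate 1 or 2 or carpel replicate 1, 1 without stamen replicate 1, 2 without carpel replicate 2), and moved by over 1.5 times in 24 of 40 omissions. MiR856 in flower stage 9 reversed to -1.17 without its replicate 1 (8.94 without replicate 2), and miR173-5p in SAM reversed to -1.17 without its replicate 2 (5.99 without replicate 1). Both miRNAs differed with the replicate number across the groups. Of the omissions' values for named contrast miRNAs 249 kept the call and 111 lost it, with the direction kept in each. Of 50 named contrast values, DESeq2 kept 46 and ended 2, all reads kept 45 and ended 5, fits on a contrast's groups alone kept 34 and ended 11, and the run without the 6 libraries kept 38 and ended 12. Of 81 named enrichments DESeq2 kept 56 and ended 25. For 7 values the miRNA was not tested under the setting. Simulated 4-fold changes were found in 0% of cases with 2 replicates against 2, and depth was not varied.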

Other observations

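Levels of whole families are given here as TMM-scaled values, without a test of the family. MiR845 was highest in seed at 11699.6 ± 5091.2 CPM, above stage 12 stamen, and lowest in juvenile leaf at 2.80 CPM. MiR165 and miR166 were highest in siliques of day 5, at 31217 ± 5867 and 74151 ± 18983 CPM, and lowest in juvenile leaf at 1876 and 6986 CPM. MiR319 was highest in the stem at the first node (233707 ± 115275 CPM) and lowest in cauline leaf (3058 CPM). MiR164 was also highest in the stem, at 60226 ± 36991 CPM. MiR447 was highest in stage 13 carpels at 67514 ± 60730 CPM. MiR390 was highest in stage 12 petals at 29005 ± 16304 CPM, and miR858, which targets MYB factors of flavonol synthesis, in stage 12 sepals at 30889 ± 38421 CPM, an SD above the mean. MiR846 was highest in green leaf embryo at 28525 ± 19755 CPM.

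Nutrient-linked families differed in where they peaked. Sulfate-linked miR395 was highest in seedling (1192 ± 71.7 CPM) and lowest in seed (1.54 CPM). Phosphate-linked miR399 was highest in flower stages 10 to 11 (13926 ± 18406 CPM, an SD above the mean) and lowest in seed (13.8 CPM), whereas miR2111 was highest in seed (749 ± 1.15 CPM) and miR827 in siliques of day 7 (3669 ± 3027 CPM). By mean log2 level miR2111b-3p peaked in seed. The more abundant miR2111a-5p peaked in flower stage 9 and miR2111a-3p in siliques of day 7. Copper-linked miR398 was highest in cauline leaf (27986 ± 4727 CPM) and stood at 191 CPM in seedling, while miR408 and miR397 were highest in siliques of day 7 (1493 ± 1021 and 916 ± 816 CPM). The most abundant miR398 member over the groups was miR398a-5p (2456 CPM). By mean log2 level it peaked in cauline leaf, as did miR398a-3p and miR398b-5p. MiR398b-3p (938 CPM over the groups) peaked in siliques of day 7. NF-YA regulator miR169 was highest in root at 47518 ± 35765 CPM, and so was miR822 at 7960 ± 4384 CPM. MiR170 and miR171 stood at 74.6 and 165 CPM in root. MiR157 was highest in hypocotyl (77552 ± 38955 CPM) and lowest in seed (155 CPM), and miR156 was high in green leaf embryo (216819 ± 59720 CPM, 16.8% of miRNA reads) and seed (16.9%) and low in stage 13 carpels (1175 CPM).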
